A study of Mus musculus with 12 samples.

How the data were processed

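RNA sequencing values were taken for 12 mouse prostate libraries in 7 groups. The mice were TRAMP animals, which carry the SV40 large T antigen under the prostate-specific probasin promoter, or wild type C57BL/6 animals. They ate AIN-93M diet, either unchanged (the control diet) or with 0.05% (w/w) phenethyl isothiocyanate (PEITC), a compound of cruciferous vegetables, and were sampled at 16 or 24 weeks of age. The labels give ventral and dorsolateral prostate as the source of 11 libraries and a tumor of unknown lobe as the source of 1.

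The deposited values are FPKM, fragment counts scaled by transcript length and library total, for 24421 genes per library, aligned to the mm10 mouse genome. The authors' notes name HISAT2, Picard, featureCounts and DESeq2 without versions or the part each played. The annotation behind the values, and the library total used in the scaling, are not given in the sources used here. The values in a library sum to between 395678 and 467650, so they were read as a relative scale. FPKM values are not counts, so no count-based test was run and depth in reads is unknown. The smallest step between values gave a relative depth only, and the deepest library was 1.57 times the shallowest. Gene positions and GC content came from GENCODE M21 (genome GRCm38, the same assembly as mm10), in which 23336 symbols (95.6%) were matched.

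Values were converted to log2(FPKM + 1). The 13375 genes with a mean of at least 0.5 FPKM over the 12 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean for each group, 5 residual degrees of freedom, moderated variances with an intensity trend, and two-sided p-values adjusted by Benjamini-Hochberg (BH). An adjusted p under 0.05 was called. The spread within the groups that hold 2 libraries stood in for that of the groups that hold 1. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. P-values measure the spread between these samples, since the labels do not state how many animals made a library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

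There were 10 comparisons: TRAMP against wild type on control diet at 24 weeks, at 16 weeks and as the mean of both ages; PEITC against control diet in TRAMP mice at 24 weeks, at 16 weeks and as the mean of both; 24 against 16 weeks in TRAMP mice on control diet; the difference of the PEITC effect and of the TRAMP effect between the ages; and the tumor against TRAMP prostate at 24 weeks. The relation of the PEITC effect to the TRAMP effect was also computed across genes. It was compared with 100 simulated draws in which PEITC had no effect, the control libraries were shared and noise was drawn separately for each gene.

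A total of 35 gene lists was fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the other settings to try. The lists covered DNA replication, mitosis, p53 targets, neuroendocrine, prostate secretory, androgen-responsive, seminal vesicle, luminal, basal, urothelial, smooth muscle, skeletal muscle, fibroblast, endothelial, adipocyte, hemoglobin, macrophage, T and NK cell, B and plasma cell and neutrophil genes. They also covered inflammatory cytokines and NF-kB targets, interferon-stimulated genes, antigen presentation, NRF2 targets, AHR targets, cholesterol synthesis, fatty acid synthesis, glycolysis, oxidative phosphorylation, endoplasmic reticulum stress and secretory pathway, apoptosis, epithelial-mesenchymal transition, DNA methylation and chromatin, mitochondrially encoded and immediate early genes. The 32 lists with at least 4 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. Camera with an estimated correlation and fry (limma), which tests whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it; fry was run without the intensity trend. Hemoglobin (1 tested member), neutrophil (1) and mitochondrially encoded genes (0) were not tested as lists.

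Named genes followed a rule. For each comparison and direction it took up to 10 called genes with the largest change whose samples did not overlap between the groups. The condition on overlap was not set for the differences of effects between the ages. Gene models without a proper name were left out. Where fewer than 5 genes were taken, the rule also took the 5 smallest p-values that did not pass. It added the 4 members with the largest change of each called list and of each list with called members, and Pbsn, Mki67, Top2a, Chga, Syp, Nqo1, Gclc, Hmox1, Cdkn1a and Dnmt1. Some genes that the rule took are not reported here. The genes set out in the text come from those. Genes of the tumor and PEITC pattern and of the seminal vesicle list that the rule did not take were chosen after their values were seen.

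The other settings fixed then were a pseudocount of 0.1 or 5, no filter or a minimum mean of 2 FPKM, scaling by median of ratios, by quantiles or with the 50 most abundant genes left out, a fit on only the groups compared, no intensity trend, robust empirical Bayes variances, a fit without the tumor library, the replicate number as a block, and each library left out in turn. A correction for GC content (loess of each library on transcript GC, span 0.5, for the 12868 tested genes with a GC value, 96.2%), the 24-week wild type libraries as the control for 16 weeks, the TRAMP effect of the other age in the relation, list medians under other scalings and 50 column orders in fry were added after seeing the data. The calling was tested on simulated data with the fitted means and spread of each gene. The noise was normal and separate for each gene, as limma assumes. The shares called therefore hold under that model and do not measure recovery in the real libraries. Of 100 genes with a mean of at least 2 FPKM that were changed 2-fold, limma called 85% for TRAMP against wild type at 24 weeks and 88% for PEITC against control diet at 24 weeks, but 76% for the tumor and 70% and 68% for the differences of the PEITC and TRAMP effects between the ages.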

Results

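Gene expression was measured by RNA sequencing of total RNA from prostates of TRAMP mice, a transgenic model of prostate cancer, and of wild type mice. TRAMP mice on control diet gave 2 libraries at 24 weeks (replicates 0 and 2) and 2 at 16 weeks, TRAMP mice on PEITC diet gave 2 at each age, and wild type mice on control diet gave 2 at 24 weeks and 1 at 16 weeks. The last library came from a tumor of a TRAMP mouse at 24 weeks. The groups with 1 library, the 16-week wild type and the tumor, have no replicates, so their values carry no error. Depth relative to the deepest library (TRAMP control diet, 24 weeks, replicate 0) ranged down to 0.635 in the 16-week wild type library, with 0.667 in replicate 0 of TRAMP PEITC at 16 weeks. It was 0.681 and 0.694 in the 24-week wild type libraries and 0.699 in the tumor. The other TRAMP prostates had 0.854 to 1, so depth was lower in wild type and tumor than in most TRAMP prostates. Between 17113 and 18505 genes had values above 0. The secretory protein gene Sbp alone took 3.10% to 3.51% of the FPKM sum in wild type libraries, 0.514% to 1.02% in TRAMP prostates and 0.171% in the tumor. Libraries of a group correlated at r = 0.9945 to 0.9962 across genes on the log2 scale, and libraries of different groups at 0.953 to 0.9974, so some resembled a library of another group more than their own replicate.

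The comparison of TRAMP with wild type mice asks what the transgene changes in the prostate. At 24 weeks Cdkn2a, a cell cycle inhibitor gene (ENSMUSG00000044303.6, mm10 chromosome 4, 89274471 to 89294653), rose from 0.480 ± 0.107 FPKM in wild type to 128 ± 11.5 in TRAMP prostates (SD, n = 2 each), a log2 fold change of 6.44 (SE 0.28, adjusted p = 4.95e-06). Genes of DNA copying rose together. Mcm3, a subunit of the replicative helicase (ENSMUSG00000041859.10, chromosome 1, 20802968 to 20820312), stood at 2.05 ± 0.250 FPKM in wild type and 48.0 ± 2.55 in TRAMP (n = 2 each). Prostate secretory genes fell: Sbp, the spermine-binding protein (ENSMUSG00000024128.13, chromosome 17, 23941672 to 23945607), went from 14387 ± 269 to 2183 ± 199 FPKM, and Pbsn, probasin (ENSMUSG00000000003.15, chromosome X, 77837901 to 77853623), from 1142 ± 676 to 45.2 ± 41.9.

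All 20 DNA replication and G1/S genes rose (20 of 20 also adjusted over the list alone; median log2 fold change 2.48), with Mcm3 at 4.01, Mcm5 at 3.79, Mcm6 at 3.50 and the licensing factor Cdt1 at 3.39. All 20 mitosis and G2/M genes rose as well (20 adjusted over the list alone; median 2.23), among them Ube2c at 3.27, Ccnb2 at 3.20, Cdk1 at 3.10 and Cdc20 at 3.09. The proliferation marker Mki67 (ENSMUSG00000031004.8, chromosome 7, 135689784 to 135716361) went from 1.21 ± 0.0351 to 14.3 ± 2.05 FPKM (n = 2 each; log2 fold change 2.78, SE 0.18), and the DNA topoisomerase gene Top2a rose by 1.62. A pseudocount of 5 lowered the log2 fold changes of genes with low values, such as Mki67 (1.63), Ube2c (2.10), Ccnb2 (1.94) and Cdk1 (1.92). Camera called both lists (adjusted p = 7.76e-17 and 2.77e-14; adjusted p = 0.428 and 0.453 with an estimated correlation).

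Of 15 interferon-stimulated genes, 14 rose (15 adjusted over the list alone; median 2.64, adjusted p = 4.21e-07; adjusted p = 0.536 with an estimated correlation). The interferon regulatory factor Irf7 (ENSMUSG00000025498.15, chromosome 7, 141262706 to 141266481) rose from 8.72 ± 5.03 to 170.1 ± 15.3 FPKM (n = 2 each), Oasl2 rose by 4.30 on the log2 scale, Isg15 by 4.18 and Usp18 by 4.17. Of 13 antigen presentation genes, 10 rose (12 adjusted over the list alone; median 1.18, adjusted p = 6.90e-06; adjusted p = 0.514 with an estimated correlation), including the immunoproteasome genes Psmb8 (2.30) and Psmb9 (2.30) and the peptide transporter Tap1 (1.95). The median of that list was 1.83 without TRAMP control 24-week replicate 0. Macrophage markers rose for 9 of 12 genes (10 adjusted over the list alone; median 1.36, adjusted p = 0.00267; adjusted p = 0.613 with an estimated correlation), with the complement gene C1qb at 1.92. Their median was 0.84 without TRAMP control 24-week replicate 2. T and NK cell markers rose for 8 of 11 (10 adjusted over the list alone; median 0.85, adjusted p = 0.00241; adjusted p = 0.564 with an estimated correlation), with the chemokine Ccl5 at 2.08. Of 15 DNA methylation and chromatin enzymes, 8 rose by either adjustment, over all genes or adjusted over the list alone (median 0.29, adjusted p = 0.00431; adjusted p = 0.453 with an estimated correlation; median 0.19 without TRAMP control 24-week replicate 0). They included Uhrf1 (2.86), the maintenance DNA methyltransferase Dnmt1 (1.82) and the histone methyltransferase Ezh2 (1.47).

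Among 13 prostate secretory genes 11 fell and 1 rose, also adjusted over the list alone (median -1.82, adjusted p = 6.37e-05; adjusted p = 0.453 with an estimated correlation). Pbsn changed by -4.87 (SE 0.73, adjusted p = 0.00127), the protease inhibitor gene Spink1 by -2.98 (-1.94 after quantile normalization), Sbpl by -2.88 and Sbp by -2.72 (-0.66 after quantile normalization). Beyond the lists, Wfdc3, which encodes a whey acidic protein domain (ENSMUSG00000076434.9, chromosome 2, 164731180 to 164745931), fell from 385 ± 96.4 to 3.09 ± 3.02 FPKM (n = 2 each; -6.77), and the calcium channel gene Trpv6 from 155.7 ± 15.8 to 8.25 ± 1.08 (-4.08). Basal epithelial markers fell for 7 of 10 genes and rose for 1, also adjusted over the list alone (median -0.97, adjusted p = 0.00450; adjusted p = 0.436 with an estimated correlation). Among them Krt5, a keratin of basal cells (ENSMUSG00000061527.7, chromosome 15, 101707070 to 101712898), changed by -2.53, Trp63 by -1.90 (-2.91 with a pseudocount of 0.1) and Krt15 by -1.41. Smooth muscle markers fell for 10 of 12 (12 adjusted over the list alone; median -1.29, adjusted p = 0.000236; adjusted p = 0.564 with an estimated correlation), with Acta2, smooth muscle actin, going from 174.7 ± 6.68 to 67.4 ± 9.62 FPKM, Myl9 at -1.46 and Lmod1 at -1.39.

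Genes of 3 further lists fell at 24 weeks by equal counts over all genes and adjusted over the list alone. They were p53 targets (7 of 12; median -0.33, adjusted p = 0.00396), with Perp at -1.33 and Ccng1 at -0.95, oxidative phosphorylation genes (11 of 18; median -0.20, adjusted p = 0.00180), with Ndufa1 at -0.66 (-0.43 after quantile normalization), and endoplasmic reticulum stress and secretory pathway genes (14 of 18; median -0.63, adjusted p = 5.99e-05), with the transcription factor Creb3l1 at -1.82 and Creld2 at -1.18. With an estimated correlation these gave adjusted p = 0.428, 0.453 and 0.453. The oxidative phosphorylation median was -0.05 after quantile normalization, -0.09 with the 50 most abundant genes left out of the scaling and -0.28 after the GC correction. The endoplasmic reticulum median was -0.34, -0.52 and -0.76 in the same order. Hmox1 changed by 0.98 (adjusted p = 0.0134; 0.0780 without TRAMP control replicate 2 and 0.0657 without wild type replicate 1), whereas Nqo1 (-0.07), Gclc (-0.11), Cdkn1a (0.42), Chga (-0.65) and Syp (-0.10) did not pass.

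The remaining lists were not called at 24 weeks. NRF2 targets had 5 higher and 7 lower members of 17 by both adjustments (adjusted over the list alone as well; median -0.11), including the glutathione transferase gene Gsta3 (-2.96) and Aldh3a1 (-2.58; -4.14 with a pseudocount of 0.1). Apoptosis regulators had 8 higher and 3 lower of 16 (median 0.21), with Bak1 at 1.08. Immediate early genes had 6 higher and 1 lower of 12 (7 and 1 adjusted over the list alone; median 0.64), and androgen-responsive genes 3 and 5 of 15 (3 and 6; median -0.32). Medians of the other immune lists were 0.82 for B and plasma cells (3 of 4 higher) and 0.46 for inflammatory cytokines and NF-kB targets (3 of 11 higher, 1 adjusted over the list alone). The luminal marker median was -0.04 (2 higher and 3 lower of 12; mean 0.10), and it turned to 0.28 with quantile normalization and 0.07 with the 50 most abundant genes left out of the scaling. Medians were -0.32 for neuroendocrine (1 of 8 lower), -0.39 for seminal vesicle (4 of 8 lower), 0.16 for urothelial (1 of 4 lower; mean -0.12), 0.35 for skeletal muscle (1 higher and 4 lower of 12), 0.44 for fibroblast (0 of 14), 1.08 for adipocyte (0 of 10) and 0.26 for epithelial-mesenchymal transition genes (1 higher and 1 lower of 12). The endothelial median of 0.18 (1 of 10 lower, 0 adjusted over the list alone) turned to -0.00 with quantile normalization. The median was 0.15 for glycolysis genes (3 higher and 2 lower of 13). For AHR targets it was -0.02 (1 of 4 lower) and for cholesterol synthesis genes -0.04 (4 higher and 2 lower of 16; mean 0.02), and these turned to 0.03 and 0.06 with the 50 most abundant genes left out. The fatty acid synthesis median of 0.01 (3 higher and 2 lower of 10) turned to -0.05 with quantile normalization and also with the GC correction.

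In all, limma called 6014 of 13375 genes at 24 weeks, 3071 higher and 2943 lower, and of these 880 rose and 362 fell at least 2-fold. Fry called 17 of the 32 lists, and camera 13. The share of called genes that were higher depended on the scaling: it was 51.1% as deposited, 66.6% with the 50 most abundant genes left out and 40.2% after the GC correction.

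**Figure D1:**
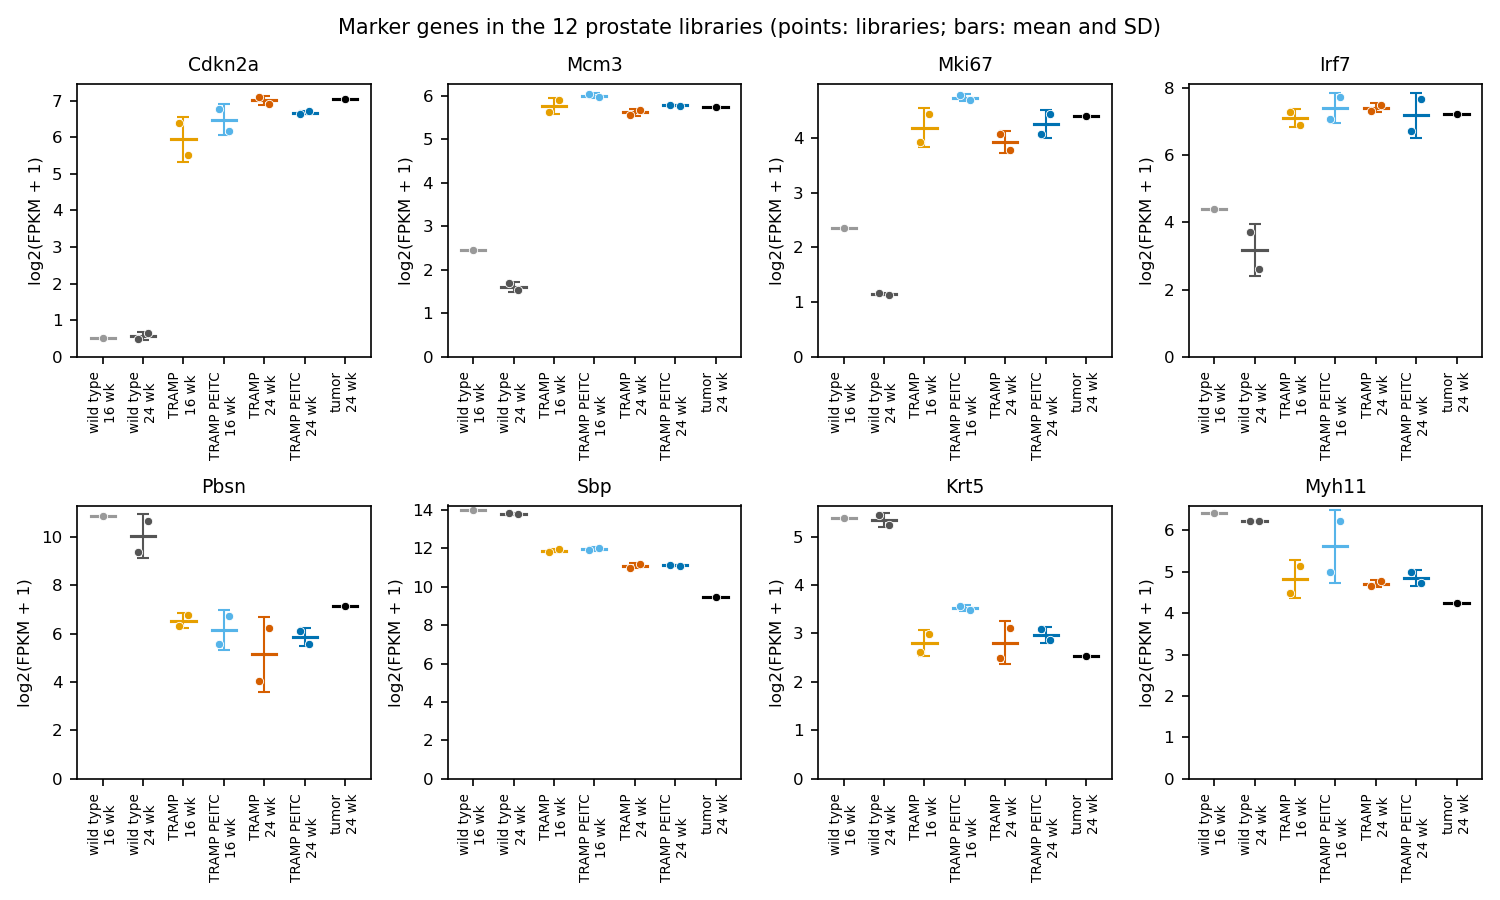
Values of 8 genes in each library as log2(FPKM + 1), by group, with points for libraries and the mean and SD of groups with 2 libraries. Cdkn2a, Mcm3, Mki67 and Irf7 lay higher in TRAMP than in wild type libraries, and Pbsn, Sbp, Krt5 and Myh11 lay lower in TRAMP mice on control diet.

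At 16 weeks, TRAMP prostates were compared with the lone 16-week wild type library. Cdkn2a stood at 63.3 ± 26.8 FPKM (SD, n = 2) in TRAMP mice and at 0.433 in that library (log2 fold change 5.42, SE 0.34). Of the 20 DNA replication genes 19 rose (19 adjusted over the list alone; median 2.15, adjusted p = 7.03e-17; adjusted p = 0.213 with an estimated correlation), with Mcm3 at 3.31, Mcm6 at 3.25 and Cdt1 at 3.11. All 20 mitosis genes rose (20 adjusted over the list alone; median 1.56, adjusted p = 1.54e-11; adjusted p = 0.406 with an estimated correlation), with Cdk1 at 2.31 and Mki67 at 1.84 (3.04 against the 24-week wild type libraries, where the list median was 2.49). Of 15 interferon-stimulated genes 14 rose by either adjustment, over all genes or adjusted over the list alone (median 1.94, adjusted p = 4.04e-06; adjusted p = 0.493 with an estimated correlation), with the antiviral gene Rsad2 at 4.43 and Usp18 at 3.75. The androgen-binding secretoglobin gene Scgb1b27 rose by 5.41, whereas Wfdc3 changed by -6.31 and Pbsn by -4.31.

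The 16-week wild type library also held transcripts of seminal vesicle secretory proteins that the other libraries nearly lacked. Svs2, a semenogelin gene (ENSMUSG00000040132.6, chromosome 2, 164235929 to 164238466), stood at 3095 FPKM in it, at 2.50 ± 0.766 in 24-week wild type (n = 2) and at 0.0557 ± 0.0787 in 16-week TRAMP prostates (n = 2). Svs5 stood at 2945 FPKM, Pate4 at 1334 and Svs4 at 372. All 8 tested members of the list were lower in TRAMP at 16 weeks (8 adjusted over the list alone; median -7.06, adjusted p = 1.54e-11; adjusted p = 0.129 with an estimated correlation). Against the 24-week wild type libraries, a control chosen after seeing the data, that median was -0.36 (adjusted p = 0.115), Svs2 changed by -1.71 instead of -11.52, Svs4 by -0.02 instead of -8.35 and Tgm4, a transglutaminase of semen, by -1.51 instead of -6.81. Skeletal muscle markers shared this dependence: 9 of 12 were lower (11 adjusted over the list alone; median -1.65, adjusted p = 4.33e-05; adjusted p = 0.493 with an estimated correlation), but their median was 0.04 against the 24-week libraries (adjusted p = 0.673).

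Further lists were called at 16 weeks. Of 13 prostate secretory genes 8 fell and 1 rose (9 and 1 adjusted over the list alone; median -1.56, adjusted p = 0.000118; adjusted p = 0.406 with an estimated correlation), with Sbpl at -2.40 and Spink1 at -2.25 (-1.28 after quantile normalization). The list median was -0.83 after quantile normalization, -1.44 with the 50 most abundant genes left out of the scaling and -1.57 after the GC correction. Basal markers fell for 8 of 10 (9 adjusted over the list alone; median -1.34, adjusted p = 4.65e-05), with Krt5 at -2.58 and Krt15 at -1.87, and p53 targets for 6 of 12 (7 adjusted over the list alone; median -0.53, adjusted p = 0.000852), with Phlda3 at -1.77. Both gave adjusted p = 0.129 with an estimated correlation. All 12 smooth muscle markers fell (12 adjusted over the list alone; median -1.49, adjusted p = 2.42e-05), with Cnn1 at -1.70, and 8 of 13 antigen presentation genes rose by either adjustment, also adjusted over the list alone (median 0.90, adjusted p = 4.33e-05), with Psmb8 at 1.81. These lists gave adjusted p = 0.493 with an estimated correlation. Chromatin enzymes rose for 8 of 15 (9 adjusted over the list alone; median 0.29, adjusted p = 0.00221; adjusted p = 0.362 with an estimated correlation), with Uhrf1 at 2.13 and Dnmt1 at 1.62. Oxidative phosphorylation genes fell for 5 of 18, also adjusted over the list alone (median -0.18, adjusted p = 0.00150; adjusted p = 0.406 with an estimated correlation). Their median was -0.02 after quantile normalization, -0.06 with the 50 most abundant genes left out of the scaling and -0.23 after the GC correction.

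The other 4 calls at 16 weeks depended on the control used or on single libraries. T and NK cell markers rose for 5 of 11 (6 adjusted over the list alone; median 0.61, adjusted p = 0.00845; adjusted p = 0.528 with an estimated correlation), with Ccl5 at 2.67, and their median was 0.38 against the 24-week wild type libraries (adjusted p = 0.112). NRF2 targets had 8 of 17 lower and 1 higher (8 and 1 adjusted over the list alone; median -0.31, adjusted p = 0.0194; adjusted p = 0.406 with an estimated correlation), with Gsta3 at -2.84. The list gave adjusted p = 0.192 against the 24-week wild type libraries and 0.0740 without TRAMP control 16-week replicate 1. Endothelial markers had 3 of 10 lower (3 adjusted over the list alone; median -0.39, adjusted p = 0.0260; adjusted p = 0.738 with an estimated correlation), and gave medians of -0.24 without TRAMP control 16-week replicate 1 (adjusted p = 0.137) and -0.01 against the 24-week libraries (adjusted p = 0.622). Endoplasmic reticulum genes had 7 of 18 lower (7 lower and 1 higher adjusted over the list alone; median -0.23, adjusted p = 0.0469; adjusted p = 0.700 with an estimated correlation). Their median turned to 0.06 with quantile normalization, and adjusted p was 0.122 without TRAMP control 16-week replicate 0.

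Limma called 4490 genes at 16 weeks, 2427 higher and 2063 lower, with 2 libraries against 1, which assumes that the lone library varies like the replicated groups. A fit on only the groups compared called 2198. Camera called 16 lists and fry 16. Against the 24-week wild type libraries 5626 genes were called, of which 3777 were among the 4490. Across genes, the log2 fold change at 16 weeks went with GC content at Spearman rho = -0.19, against 0.03 at 24 weeks. With the 50 most abundant genes left out of the scaling the median of all genes shifted by 0.10 at 16 weeks, and 70.3% of the called genes were higher in place of 54.1%. No called list median changed its sign with that scaling.

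The TRAMP effects at the 2 ages, which share no library, were alike. Among genes called at both ages 1828 were higher at both (557 expected of independent lists), 1552 were lower at both (454 expected) and 21 went opposite ways. The calls at both ages use the same spread of each gene, so the lists are not fully independent even without a common effect. The log2 fold changes correlated at r = 0.733 across 13375 genes, which are not independent replicates. As the mean of both ages, 7054 genes were called, 3591 higher and 3463 lower, or 6606 with the 24-week wild type libraries alone as control, 6033 of them shared. Cdkn2a, Mcm3 and Mki67 were among the genes that rose, the last by 2.31 (SE 0.14), and Cyp2b10, a cytochrome P450 gene named after its value was seen, changed by -2.03 (SE 0.06). With the 50 most abundant genes left out the median shifted by 0.10 and 67.3% of called genes were higher in place of 50.9%, whereas the share was 46.6% with quantile normalization and 44.5% after the GC correction.

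For the mean of both ages camera called 15 lists, with adjusted p from 4.33e-15 to 0.0129, and from 0.240 to 0.735 with an estimated correlation, and fry called 18. The counts over all genes given here were equal adjusted over the list alone, except where a second is given. Higher lists were DNA replication (20 of 20 genes, median 2.38), mitosis (20 of 20, 1.95), interferon-stimulated (15 of 15, 2.32), antigen presentation (12 of 13, 1.04), T and NK cell (10 of 11, 0.73), macrophage (8 of 12, 1.11) and chromatin enzyme genes (8 of 15, or 9 adjusted over the list alone, 0.20). Lower lists were secretory (12 of 13 with 1 higher, -1.93), basal (8 of 10 with 1 higher, -1.15), smooth muscle (12 of 12, -1.38), p53 targets (8 of 12, -0.42), oxidative phosphorylation (12 of 18, -0.20) and endoplasmic reticulum genes (11 of 18, -0.44). After quantile normalization the medians were -0.89 for secretory, -0.05 for oxidative phosphorylation and -0.14 for endoplasmic reticulum genes. In the same order they were -1.82, -0.09 and -0.33 with the 50 most abundant genes left out, and -1.97, -0.26 and -0.51 after the GC correction. Seminal vesicle (8 of 8, -3.54) and skeletal muscle genes (8 of 12, -0.70) were also called lower, but gave -0.37 (adjusted p = 0.102) and 0.20 (adjusted p = 0.889) without the 16-week wild type library.

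The comparison of PEITC with control diet asks what the compound changes in TRAMP prostates. At 24 weeks no gene passed. The 20 DNA replication genes had a median log2 fold change of 0.19, with 19 above 0, and the 20 mitosis genes a median of 0.22, with 19 above 0; Mki67 stood at 14.3 ± 2.05 FPKM on control diet and 18.2 ± 3.34 with PEITC (SD, n = 2 each; 0.33), and Top2a at a log2 fold change of 0.31. Genes with the smallest p-values among those lower were Ptx3, a soluble pattern recognition receptor (1.36 FPKM on control diet and 0.0961 with PEITC; -1.10, SE 0.16), Krt6a, a keratin of stressed epithelium (-1.59, SE 0.25), Sfn (-0.76), Ssbp4 (-0.58) and Clca3a2 (ENSMUSG00000028262.13, chromosome 3, 144796559 to 144819494), at 26.6 ± 15.2 FPKM on control diet and 0.747 ± 0.0497 with PEITC (-3.86, SE 0.61). Those higher were the clock gene Per3 (0.49, SE 0.08), Cyp2b10 (0.44), Lhfpl1 (0.44), Ctgf (1.23) and Havcr1 (0.79). The NRF2 targets Nqo1 (-0.12), Gclc (0.06) and Hmox1 (-0.67) did not pass, nor did Dnmt1 (0.08), Pbsn (0.70) or Cdkn1a (-0.69). The NRF2 target list had a median of -0.00, which was 0.04 with quantile normalization.

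Limma called 0 genes at 24 weeks (smallest adjusted p = 0.415), with 1267 at an unadjusted p under 0.05 against 669 expected by chance. It called 160 without TRAMP control replicate 2, Ssbp4, Sfn, Clca3a2 and Krt6a among them, and 25 without PEITC replicate 0, with Chga, Insm1, Snap25 and Syp among them. Fry called 0 lists and camera 8, none of them with an estimated correlation (adjusted p = 0.872 for each). The log2 fold changes went with GC content across genes at rho = -0.31.

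DNA replication (adjusted p = 9.18e-06) and mitosis (adjusted p = 0.000433) were called higher, though the mitosis median was 0.00 without PEITC replicate 1 (adjusted p = 0.886), 0.48 without PEITC replicate 0, 0.35 without control replicate 0 and 0.13 without control replicate 2 (adjusted p = 0.204). All 8 neuroendocrine markers were above 0 (median 0.76, adjusted p = 0.0116), a value that rested on PEITC replicate 1: it was -0.01 without that library (adjusted p = 0.997) and 1.34 without replicate 0. In it the granin gene Chga stood at 12.4 FPKM and the neuroendocrine transcription factor gene Insm1 at 10.8, against a mean of 0.137 FPKM of Chga on control diet. No member of any of these lists passed over all genes, and 0 passed adjusted over the list alone.

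Camera called 5 lists lower at 24 weeks, also with 0 members over all genes. Luminal markers had a median of -0.20 (1 member adjusted over the list alone; adjusted p = 0.0137, or 0.0590 without control replicate 2 and 0.0702 after the GC correction). Glycolysis genes had -0.18 (adjusted p = 0.0116, or 0.0702 after the GC correction), cholesterol synthesis genes -0.09 (adjusted p = 0.0157, or 0.0839 without control replicate 2), and inflammatory genes -0.25 with 0 of 11 above 0 (adjusted p = 0.0448). The inflammatory median was -0.16 without control replicate 2 (adjusted p = 0.248), and adjusted p was 0.291 without PEITC replicate 0. Endothelial markers had a median of -0.20 (adjusted p = 0.0448, or 0.0592 after the GC correction), which was -0.09 without control replicate 2 (adjusted p = 0.628), -0.08 without PEITC replicate 0 (adjusted p = 0.608), -0.35 without control replicate 0 and -0.39 without PEITC replicate 1.

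At 16 weeks Cyp2b10, a cytochrome P450 of xenobiotic metabolism (ENSMUSG00000030483.14, chromosome 7, 25897620 to 25926624), fell from 47.6 ± 1.42 FPKM on control diet to 25.7 ± 2.26 with PEITC (SD, n = 2 each; log2 fold change -0.86, SE 0.07, adjusted p = 0.0395). Its call was lost without any of the 4 libraries (adjusted p = 0.107 to 0.453) and without the intensity trend (adjusted p = 0.142). All 20 DNA replication genes were above 0 (median 0.18) and 19 of 20 mitosis genes (median 0.19), with Mki67 at 17.5 ± 4.55 FPKM on control diet and 25.8 ± 1.33 with PEITC (n = 2 each; 0.55, adjusted p = 0.438). Basal markers had a median of 0.36, with Krt5 at 6.06 ± 1.29 and 10.5 ± 0.472 FPKM, and the 12 smooth muscle markers, all above 0, had a median of 0.54. Nqo1 (-0.05), Gclc (0.05), Hmox1 (-0.09), Top2a (0.32) and Dnmt1 (0.40) did not pass, and the NRF2 list had a median of -0.09. The smallest p-values among other genes belonged to H1fx (0.74), Mir8091 (0.65), Erdr1 (1.26), Cenpb (0.45) and Lgals7 (0.77), and to Acadsb (-0.39), Chordc1 (-0.57), Vamp7 (-0.49), Tiprl (-0.31) and Mir6362, listed at 0 in both PEITC libraries.

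Limma called 1 gene at 16 weeks, with 1347 at an unadjusted p under 0.05, and the log2 fold changes went with GC content at rho = 0.36. Camera called 5 lists and fry 0, and none held with an estimated correlation (adjusted p = 0.262 for the basal list and 0.979 for the others). The called lists were DNA replication (adjusted p = 1.73e-06; median 0.09 without control replicate 0 and 0.31 without control replicate 1), mitosis (adjusted p = 0.000251), smooth muscle (adjusted p = 1.93e-05; median 0.10 without PEITC replicate 1, adjusted p = 0.439, and 1.03 without PEITC replicate 0) and basal markers (adjusted p = 1.93e-05), of which 4 of 10 were higher adjusted over the list alone and 0 over all genes. Endoplasmic reticulum genes were called lower (median -0.09, 1 of 18 adjusted over the list alone; adjusted p = 0.0252). Their adjusted p was 0.322 without control replicate 1 and 0.141 without PEITC replicate 0, and their median was -0.17 without control replicate 0 and -0.14 without PEITC replicate 1, and -0.13 after the GC correction.

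As the mean of both ages, the 20 DNA replication genes had a median of 0.20 with PEITC and the 20 mitosis genes 0.22, all 40 above 0. No gene passed over all genes, while 10 of the 20 replication genes passed adjusted over the list alone. Mki67 stood at 0.44 (SE 0.13), the histone gene H1fx at 0.52, Havcr1 at 0.63, Nab2 at 0.32, Lgals7 at 0.53 and Ank at 0.50. Lower values were those of Clca3a2 (-2.10), the matrix protease Mmp3 (-0.99), S100a14 (-0.46), Podxl (-0.39) and Wars (-0.35). Limma called 0 genes (smallest adjusted p = 0.735), with 889 at an unadjusted p under 0.05, and fry called 0 lists. It called 16 genes without PEITC 24-week replicate 0 and 5 without control 24-week replicate 2.

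Camera called 7 lists for the mean of both ages. With an estimated correlation the replication and basal lists gave adjusted p = 0.691 and the others adjusted p = 0.952. They were DNA replication (adjusted p = 2.94e-13), mitosis (adjusted p = 6.33e-09; median 0.34 without PEITC 24-week replicate 0 and 0.10 without replicate 1), basal (median 0.20, 1 member adjusted over the list alone, adjusted p = 0.0153, or 0.0745 without PEITC 16-week replicate 0) and smooth muscle markers (0.25, all 12 above 0, adjusted p = 0.00420). The smooth muscle median was 0.03 without PEITC 16-week replicate 1 (adjusted p = 0.960) and 0.47 without replicate 0. The neuroendocrine median of 0.45 (adjusted p = 0.0387) was 0.04 without PEITC 24-week replicate 1 (adjusted p = 0.555) and 0.77 without replicate 0. Its call was also lost without control 24-week replicate 0 (adjusted p = 0.109), control 16-week replicate 1 (0.160) and PEITC 16-week replicates 0 (0.109) and 1 (0.0531). Endothelial markers (-0.19, adjusted p = 0.0387) lost their call without control 24-week replicate 2 (adjusted p = 0.355), PEITC 24-week replicate 0 (0.328), control 16-week replicate 0 (0.317) and PEITC 16-week replicate 0 (0.529). Glycolysis genes (-0.08, adjusted p = 0.0153) lost theirs without control 16-week replicate 0 (adjusted p = 0.228) and PEITC 16-week replicate 0 (0.109), and had a median of -0.14 without control 16-week replicate 1.

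**Figure D2:**
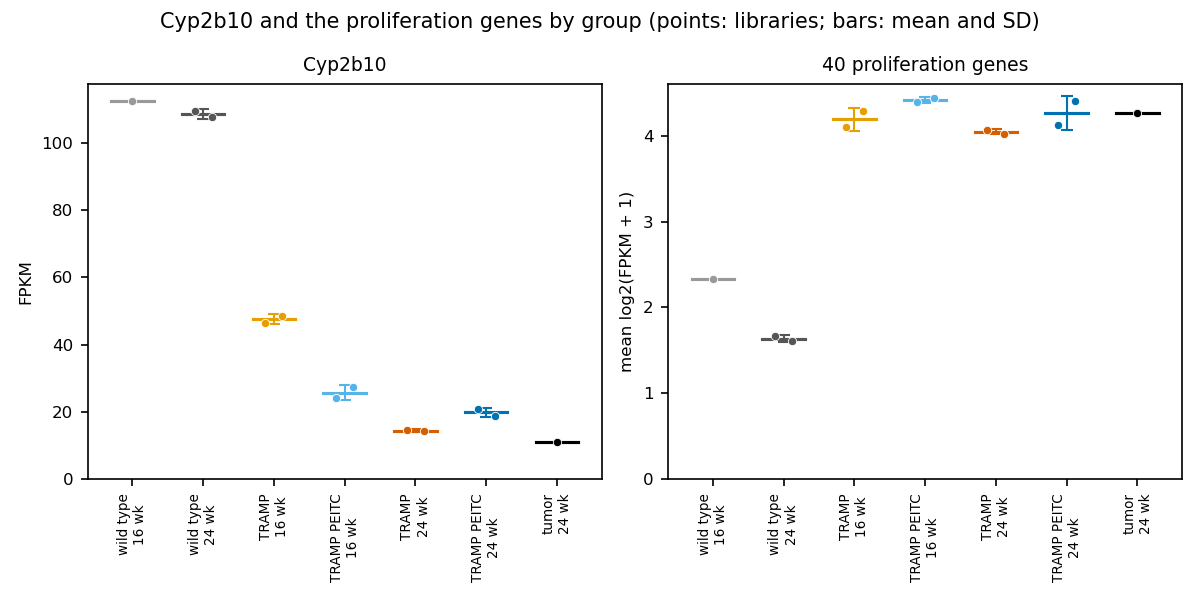
FPKM of Cyp2b10 and the mean log2(FPKM + 1) of 40 proliferation genes in each library, by group, with points for libraries and the mean and SD of groups with 2 libraries. Cyp2b10 stood at 47.6 FPKM in TRAMP mice on control diet at 16 weeks and 25.7 with PEITC, and the proliferation mean was 4.07 and 4.03 on control diet against 4.13 and 4.41 with PEITC at 24 weeks.

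Age was compared in TRAMP mice on control diet. Cyp2b10 fell from 47.6 ± 1.42 FPKM at 16 weeks to 14.4 ± 0.369 at 24 weeks (SD, n = 2 each; log2 fold change -1.66, SE 0.07, adjusted p = 0.000265) and was the only gene that limma called. That call was lost in a fit on only the groups compared, which leaves fewer samples for the spread. Prostate secretory genes were lower at 24 weeks as a list, with Sbp at 3765 ± 235 FPKM at 16 weeks and 2183 ± 199 at 24 weeks (-0.79, not passing). Endoplasmic reticulum genes, cholesterol synthesis genes and DNA replication genes were also called lower as lists, and T and NK cell, macrophage, B and plasma cell, endothelial and adipocyte markers higher. None of these 9 calls held with an estimated correlation (smallest adjusted p = 0.795), and the higher ones were lost without TRAMP control 24-week replicate 2. Genes with small p-values that did not pass were Ssbp4 (0.71), Ptx3 (1.19), the transcription factor Sox9 (0.58), the retinoic acid receptor Rara (0.61), Spsb2 (0.42), the oxidoreductase Ero1l (-0.64), Tmed2 (-0.44) and the cholesterol synthesis genes Msmo1 (-0.37) and Idi1 (-0.49).

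At an unadjusted p under 0.05 limma gave 2261 genes for age. It called 260 genes without TRAMP control 24-week replicate 2 and 2 without replicate 0. The log2 fold changes went with GC content at rho = 0.44. Camera called 9 lists and fry 1; with an estimated correlation cholesterol synthesis gave adjusted p = 0.795 and the others adjusted p = 0.969. The lower lists were endoplasmic reticulum genes (median -0.26, 8 of 18 adjusted over the list alone, adjusted p = 5.79e-06), secretory genes (-0.71, 3 of 13 adjusted over the list alone, adjusted p = 0.000530; -0.23 without TRAMP control 24-week replicate 0), cholesterol synthesis genes (-0.17, 6 of 16 adjusted over the list alone, adjusted p = 0.00446; -0.27 without 16-week replicate 0) and DNA replication genes (-0.16, adjusted p = 0.0143). The replication call was lost without 24-week replicate 0 (adjusted p = 0.176) and without 16-week replicate 1 (median 0.01, adjusted p = 0.776), and the median was -0.27 without 16-week replicate 0.

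The higher lists for age rested on single libraries, and none of their members passed over all genes. T and NK cell markers had a median of 0.43 (1 member adjusted over the list alone, adjusted p = 0.00195), which was 0.28 without 24-week replicate 2 (adjusted p = 0.129). Macrophage markers had 0.53 (adjusted p = 0.0191), which was 0.05 without 24-week replicate 2 (adjusted p = 0.991), 0.09 without 16-week replicate 1 (adjusted p = 0.874), 1.05 without 24-week replicate 0 and 1.03 without 16-week replicate 0. B and plasma cell markers had 0.57 (adjusted p = 0.0274, or 0.358 without 24-week replicate 2 and 0.318 without 16-week replicate 1). Adipocyte markers had 1.33 (adjusted p = 0.0448), which was 0.72 without 24-week replicate 2 (adjusted p = 0.762), 0.80 without 16-week replicate 1 (adjusted p = 0.622) and 2.13 without 24-week replicate 0. Endothelial markers had 0.17 (adjusted p = 0.0448, or 0.580 without 24-week replicate 2 and 0.694 without 16-week replicate 1), with 0.35 without 24-week replicate 0 and 0.40 without 16-week replicate 0.

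The difference of the PEITC effect between the ages was tested directly. Cyp2b10 was the only gene called: its PEITC effect was 0.44 at 24 weeks and -0.86 at 16 weeks, a difference of 1.30 (SE 0.10, adjusted p = 0.0245). The 16-week control libraries enter this test, the PEITC test at 16 weeks and the age test, so the Cyp2b10 calls are not independent. The 24-week control libraries likewise enter this test, the PEITC test at 24 weeks and the age test, in all of which Ptx3 and Ssbp4 were named. The call was lost without TRAMP control 24-week replicate 0 (adjusted p = 0.137), PEITC 24-week replicate 1 (0.0901), control 16-week replicates 0 (0.180) and 1 (0.246) and PEITC 16-week replicate 0 (0.0926). Genes that did not pass included the splicing factors Srsf10 (0.72) and Tra2b (0.53), Zfp874a (0.83), Chordc1 (0.85), the small nucleolar RNA Snora34 (-1.54), Cenpb (-0.64), Ptx3 (-1.27), the mitochondrial carrier Slc25a10 (-0.41) and Ssbp4 (-0.68). Limma gave 1720 genes at an unadjusted p under 0.05, and called 124 without control 24-week replicate 2 and 14 without PEITC 24-week replicate 0. The differences went with GC content at rho = -0.43.

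Camera called 5 lists for that difference and fry 0, with adjusted p = 0.493 for basal and cholesterol synthesis genes and 0.994 for the others with an estimated correlation. Basal markers had a median difference of -0.40 (2 of 10 adjusted over the list alone, adjusted p = 0.00218). Smooth muscle markers had -0.54 (adjusted p = 0.00583), which was -0.11 without PEITC 16-week replicate 1 (adjusted p = 0.411) and -1.01 without replicate 0. That call was also lost without control 24-week replicate 2 (adjusted p = 0.0731) and control 16-week replicate 0 (0.0500). Cholesterol synthesis genes had -0.14 (2 of 16 adjusted over the list alone, adjusted p = 0.0125, or 0.0588 without PEITC 16-week replicate 1; -0.09 without control 24-week replicate 2). Luminal markers had -0.24 (adjusted p = 0.0193, or 0.213 without control 16-week replicate 1, 0.0588 without PEITC 16-week replicate 1 and 0.196 after the GC correction). Endoplasmic reticulum genes had 0.14 (adjusted p = 0.0325), which was 0.07 without control 24-week replicate 0 (adjusted p = 0.315). This call was also lost without PEITC 24-week replicate 0 (adjusted p = 0.0854), control 16-week replicate 1 (0.201) and PEITC 16-week replicate 0 (0.0946).

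The difference of the TRAMP effect between the ages was called for 49 genes, 44 above 0 and 5 below. The largest were genes high in the 16-week wild type library: Svs2 (9.76), Pate4 (9.65), Svs4 (8.29), the protease gene Plau (5.52, with 57.2 FPKM in that library) and Pfkfb3 (4.32). Svs5 was also called, and is listed at 0 in TRAMP mice on control diet at 24 weeks. With a pseudocount of 0.1, Svs4 gave adjusted p = 0.0672 and Svs5 0.149. Those below 0 were Scgb2b12 (-3.07), Scgb2b27 (-2.25), Cyp2b10 (-1.61, adjusted p = 0.000772), Tbccd1 (-0.70) and Erlec1 (-0.62). Tbccd1 lost its call without each of the 6 replicated libraries compared (adjusted p = 0.0654 to 0.133), and Erlec1 without each of them but TRAMP control 24-week replicate 2 (adjusted p = 0.0590 to 0.149). Scgb2b12 lost its call without TRAMP control 24-week replicate 0 (adjusted p = 0.0598), control 16-week replicate 1 (0.1001) and wild type 24-week replicate 0 (0.0525), and Scgb2b27 without wild type 24-week replicate 0 (0.0637) or 1 (0.0736). Mitosis genes differed by a median of 0.73 (20 of 20 above 0, 9 adjusted over the list alone, adjusted p = 2.52e-10; adjusted p = 0.853 with an estimated correlation) and DNA replication genes by 0.25 (5 adjusted over the list alone, adjusted p = 0.000681; adjusted p = 0.853 with an estimated correlation; median 0.12 without control 16-week replicate 0, 0.16 without wild type 24-week replicate 1 and 0.15 after the GC correction). In the wild type libraries Mki67 stood at 4.09 FPKM at 16 weeks and 1.21 ± 0.0351 at 24 weeks (n = 2).

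Limma gave 2108 genes at an unadjusted p under 0.05 for this difference, and called 82 without TRAMP control 24-week replicate 2. The differences went with GC content at rho = 0.32. Camera called 9 lists and fry 1. With an estimated correlation seminal vesicle genes gave adjusted p = 0.0846, macrophage markers 0.904, epithelial-mesenchymal transition genes 0.874 and the others 0.853. Seminal vesicle genes differed by 7.03 (7 of 8 called, adjusted p = 1.93e-20), skeletal muscle markers by 1.45 (1 of 12, 7 adjusted over the list alone, adjusted p = 1.60e-06), endothelial markers by 0.54 (2 of 10 adjusted over the list alone, adjusted p = 0.000892), endoplasmic reticulum genes by -0.25 (4 of 18 adjusted over the list alone, adjusted p = 0.00141; -0.12 without TRAMP control 24-week replicate 0 and -0.38 after the GC correction) and immediate early genes by 0.72 (3 of 12 adjusted over the list alone, adjusted p = 0.000681; 0.46 without TRAMP control 16-week replicate 1 and 0.39 without wild type 24-week replicate 1). Macrophage markers differed by 0.79 (adjusted p = 0.0211), which was 0.29 without TRAMP control 24-week replicate 2 (adjusted p = 0.528), 0.33 without 16-week replicate 1 (adjusted p = 0.400), 1.29 without 24-week replicate 0 and 1.27 without 16-week replicate 0, with adjusted p = 0.0525 without wild type 24-week replicate 1. Epithelial-mesenchymal transition genes differed by 0.31 (adjusted p = 0.0347), which was 0.14 without TRAMP control 24-week replicate 2 (adjusted p = 0.507), 0.60 without replicate 0 and 0.52 without 16-week replicate 0. That call was also lost without TRAMP control 16-week replicate 1 (adjusted p = 0.151) and wild type 24-week replicates 0 (0.0507) and 1 (0.0670).

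The tumor was compared with TRAMP prostates on control diet at 24 weeks. The labels give its lobe as unknown, so differences between lobes were not separated from those of the tumor. The keratin genes Krt6a and Krt17 were higher in it, while the basal epithelial list was not called (median 0.25, adjusted p = 0.0568). Krt6a stood at 25.9 FPKM in the tumor and 2.36 ± 1.09 in prostates (SD, n = 2; log2 fold change 3.04, SE 0.31, adjusted p = 0.00314), and Krt17 at 52.8 and 5.91 ± 0.800 (2.97). The fibrinogen genes Fgb (ENSMUSG00000033831.5, chromosome 3, 83040141 to 83049863; 17.0 FPKM against 0.933 ± 0.845; 3.29, SE 0.31) and Fgg (2.54) also rose, as did Cda (2.78), the matrix protein genes Thbs1 (2.34), Ctgf (2.33) and Tnc (2.28), and the cytokine gene Il11 (2.28). Of the genes named for a large fall, 4 encode secretoglobins. Scgb1b27 stood at 3.28 FPKM in the tumor and 54.1 ± 6.69 in prostates (-3.68, SE 0.64), and Scgb2b12 changed by -2.96, Scgb2b7 by -2.92 and Scgb1b20 by -2.91. Crabp1, a retinoic acid binding protein, changed by -3.27 (SE 0.19, adjusted p = 0.000560), and C2cd4a by -3.63.

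Camera called 8 lists in the tumor, none of them with an estimated correlation (adjusted p = 0.544 for p53 targets and 0.788 for the others). Immediate early genes were higher in the tumor (median 0.79, 1 of 12 called, 2 adjusted over the list alone, adjusted p = 0.000798), with Ier3 at 2.09, as were mitosis genes (0.39, all 20 above 0, 1 called and 0 adjusted over the list alone, adjusted p = 0.00151), p53 targets (0.25, 4 of 12 called, 5 adjusted over the list alone, adjusted p = 0.00544), with Trp53inp1 at 1.14, and apoptosis regulators (0.16, 4 of 16 called, 5 adjusted over the list alone, adjusted p = 0.00721), with Apaf1 at 0.69. Endothelial markers had a median of 0.82 (4 of 10 called; 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.00250), with Emcn at 1.43 (adjusted p = 0.0554 without TRAMP control 24-week replicate 0). Epithelial-mesenchymal transition genes had 0.70 (1 of 12 called, 1 adjusted over the list alone, adjusted p = 0.00852), with Snai1 at 1.12; their median was 0.28 without TRAMP control 24-week replicate 0 (adjusted p = 0.110) and 1.12 without replicate 2. Secretory genes were lower (median -0.72, 6 of 13 called, 6 adjusted over the list alone, adjusted p = 0.00151), with Sbpl at -2.23, Spink1 at -2.23 and Spink5 at -1.69. Endoplasmic reticulum genes had -0.29 (4 of 18 lower; 7 lower and 1 higher adjusted over the list alone; adjusted p = 0.0365), which was -0.15 without replicate 2 (adjusted p = 0.200).

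Limma called 1573 genes in the tumor, 748 higher and 825 lower, with 1 library against 2, which assumes that the tumor varies like the replicated groups, while a fit on only these 3 libraries called 0 (smallest adjusted p of the genes named here, 0.110). Fry called 4 lists. Log2 fold changes of genes with low values depended on the pseudocount: with 5 in place of 1, Fgb changed by 1.90, Fgg by 1.22, Tnc by 1.26, Il11 by 0.997, C2cd4a by -1.90, Snai1 by 0.40 and Apaf1 by 0.44. Cdkn1a rose by 1.55 in the tumor, but its call was lost without either TRAMP control library (adjusted p = 0.0768 and 0.0884).

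Several genes high in the tumor were also lower with PEITC than on control diet in TRAMP prostates at 24 weeks, although none passed that test. The iron-binding protein gene Lcn2 stood at 400.3 FPKM in the tumor, at 87.9 ± 37.7 on control diet and at 10.7 ± 0.376 with PEITC (SD, n = 2 each). The acute-phase genes Lrg1 and Saa1 stood at 877 and 74.6 FPKM in the tumor, at 357 ± 263 and 53.3 ± 65.4 on control diet and at 21.5 ± 2.01 and 1.27 ± 0.0928 with PEITC (n = 2 each). They were not confined to TRAMP mice, since Lcn2 stood at 135 FPKM in wild type 24-week replicate 0, 11.4 in replicate 1 and 114 in the 16-week wild type library. The protease inhibitor gene Timp1 stood at 165 FPKM in the tumor, 30.2 ± 1.34 on control diet and 5.03 ± 0.0747 with PEITC (n = 2 each).

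**Figure D3:**
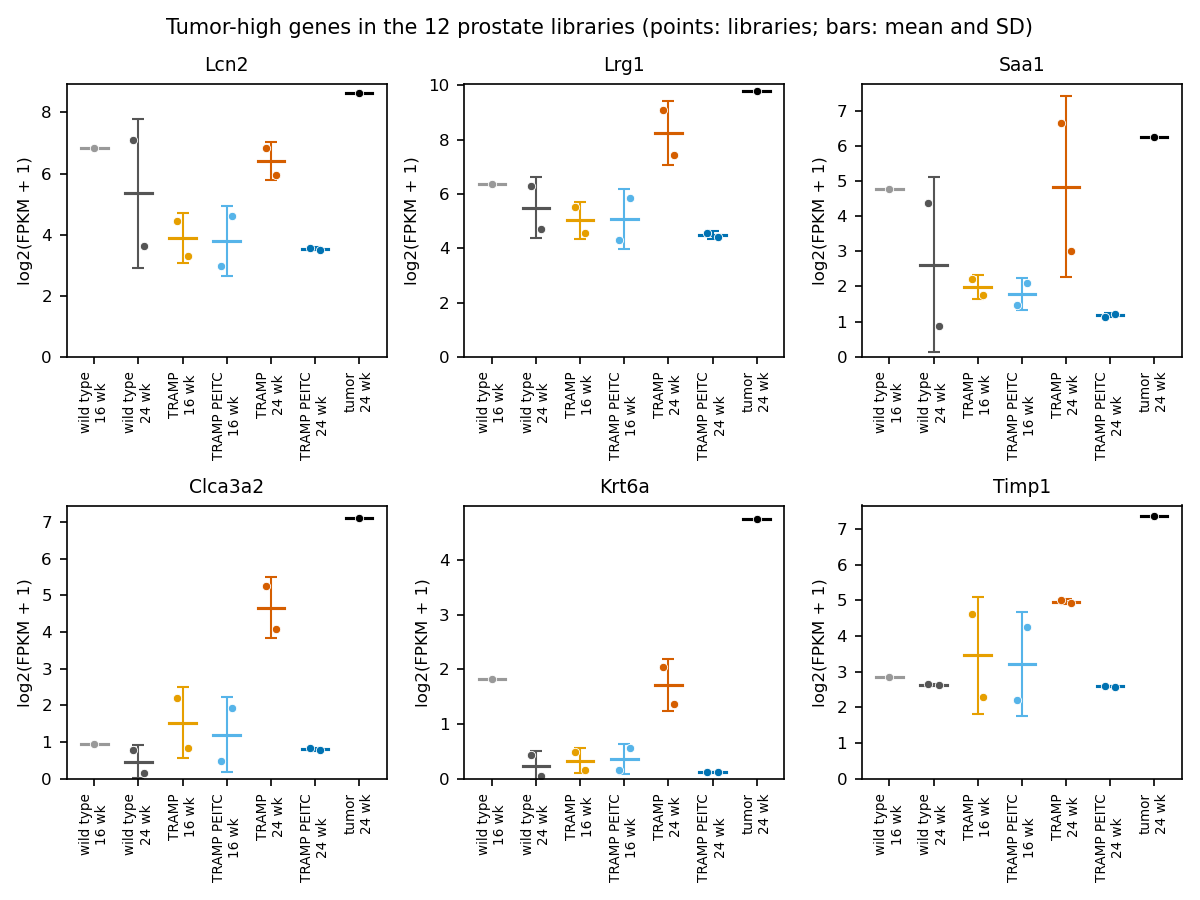
Values of 6 genes high in the tumor (Lcn2, Lrg1, Saa1, Clca3a2, Krt6a and Timp1) as log2(FPKM + 1) in each library, by group, with points for libraries and the mean and SD of groups with 2 libraries. Clca3a2 stood at 136 FPKM in the tumor and at 26.6 ± 15.2 and 0.747 ± 0.0497 on control and PEITC diet at 24 weeks.

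**Figure D4:**
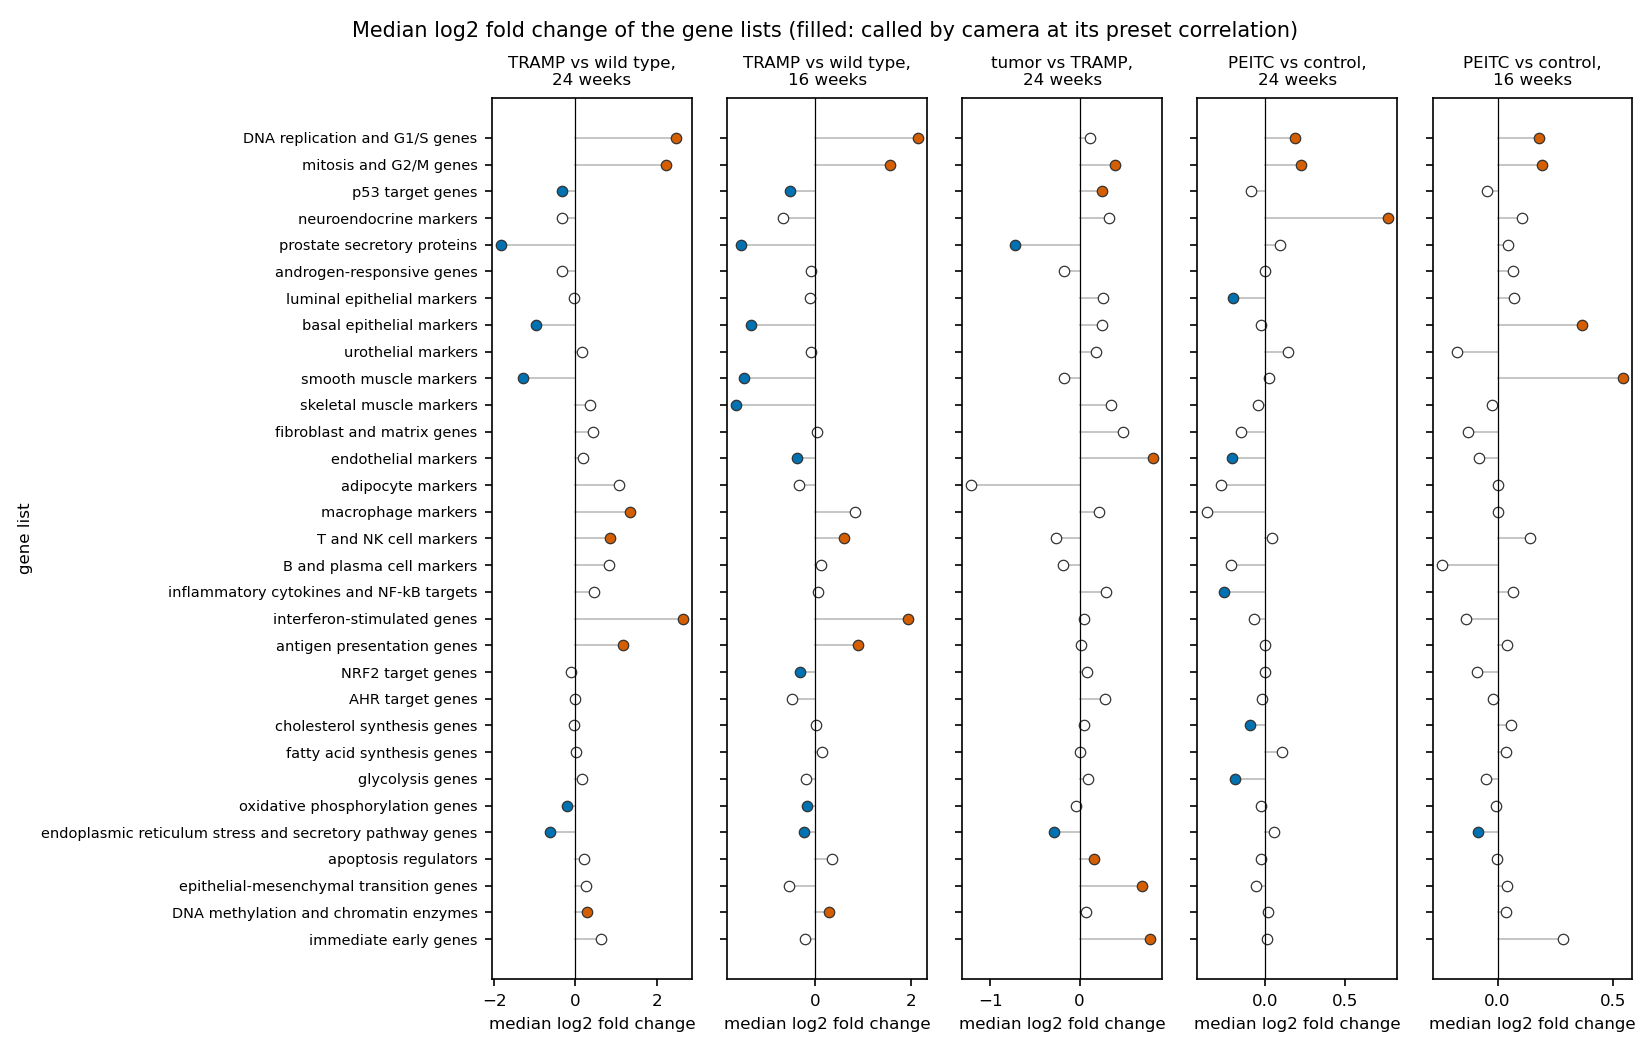
Median log2 fold change of 31 gene lists in 5 comparisons, with filled points for lists that camera called at the preset correlation; the horizontal axes differ between panels and the seminal vesicle list is not drawn. DNA replication genes had medians of 2.48 in TRAMP against wild type at 24 weeks and 0.19 with PEITC at 24 weeks.

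Whether PEITC moved genes against the TRAMP effect was computed across the genes called in TRAMP and across all tested genes. At 24 weeks the PEITC and TRAMP log2 fold changes correlated at r = -0.199 across 6014 genes, against -0.0779 simulated with shared control libraries and no PEITC effect. Of these genes 51.4% went opposite ways against 50.03% simulated. The simulation kept the set of called genes fixed and drew noise separately for each gene. It left out the choice of those genes by the same libraries and any noise shared between genes. The excess over it therefore does not decide whether PEITC opposed the TRAMP effect. Across all 13375 tested genes r was -0.186 against -0.122 simulated, and 52.8% went opposite ways, below the 54.2% simulated. With the TRAMP effect of 16 weeks, which shares no library with the PEITC effect at 24 weeks and was chosen after seeing the data, r turned to 0.195 across 4490 genes and 32.2% went opposite ways (r = 0.104 across all tested genes). At 16 weeks r was -0.201, against -0.0687 simulated in the same way, with 59.2% opposite against 50.1% simulated. Across all tested genes r was then -0.159 against -0.121 simulated, with 56.3% opposite against 54.1%. The covariance beyond the simulated one was -0.0341 at 24 weeks and -0.0304 at 16 weeks across the genes called in TRAMP, but -0.0143 and -0.00523 across all tested genes. With the TRAMP effect of 24 weeks, r at 16 weeks was -0.0064 with 48.1% opposite (r = -0.0217 across all tested genes). These alternatives change the age of the TRAMP effect as well as the sharing of libraries, and across called genes also the genes. They change the relation to GC content too: rho was -0.31 for PEITC and 0.03 for TRAMP at 24 weeks, and 0.36 and -0.19 at 16 weeks. The relation to the other age was not computed after the GC correction. The alternatives therefore do not separate age, sharing and GC content, and genes are not independent replicates. At 24 weeks r was -0.0618 without PEITC replicate 0, -0.0966 without wild type replicate 1, -0.304 without PEITC replicate 1 and -0.327 without control replicate 2. At 16 weeks r was -0.0687 without PEITC replicate 1 and -0.320 without control replicate 1.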

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

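The luminal marker test, both seminal vesicle tests, the GC correction and the permutation of the proliferation score were chosen after the results were seen. Direct tests of the difference between the ages called the PEITC effect different for 1 gene, Cyp2b10, by 1.30 on the log2 scale. They called it different for 5 lists, by medians of -0.24 for luminal, -0.40 for basal and -0.54 for smooth muscle markers, -0.14 for cholesterol synthesis genes and 0.14 for endoplasmic reticulum genes. Single libraries carry several of these: the Cyp2b10 call was lost without 5 of the 8 libraries in turn, smooth muscle was -0.11 or -1.01 without PEITC 16-week replicate 1 or 0, and without the former 2 of the 5 list calls were left. The TRAMP effect was called different between the ages for 49 genes, and for 9 lists by medians of 0.25 for DNA replication, 0.73 for mitosis, 7.03 for seminal vesicle, 1.45 for skeletal muscle, 0.54 for endothelial, 0.79 for macrophage, -0.25 for endoplasmic reticulum, 0.31 for epithelial-mesenchymal transition and 0.72 for immediate early genes. None of these lists was called with an estimated correlation. The differences of the TRAMP effect rest on the lone 16-week wild type library, which is assumed to vary like the replicated groups and holds seminal vesicle transcripts. In TRAMP mice themselves the replication and mitosis medians were -0.16 and -0.13 at 24 against 16 weeks, the second not called. With the 24-week wild type libraries as control, the 16-week medians were 2.64 and 2.49, above the 2.48 and 2.23 at 24 weeks.

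Proliferation genes had median differences above 0 with PEITC at both ages, 0.200 at 24 weeks (38 of 40 genes above 0) and 0.189 at 16 weeks (39 of 40). None of the 40 passed over all genes, and fry called 0 lists. The camera calls of both lists were lost with an estimated correlation (adjusted p = 0.872 at 24 weeks and 0.979 at 16 weeks). That setting called 0 lists in every comparison, so this loss does not tell these lists from others. The mean log2(FPKM + 1) of the 40 genes was 4.34 ± 0.144 with PEITC and 4.12 ± 0.115 on control diet (SD, n = 4 each), and an exact two-sided permutation test gave p = 0.0571 over 70 arrangements and p = 0.0556 over the 36 within ages, the smallest that the test within ages can give. GC content bias as the whole cause was argued against, since the medians after the GC correction were at least 0.980 times those before. A higher share of luminal epithelium as the whole cause was argued against. Luminal markers stood below proliferation genes at both ages, by -0.12 at the age where they came closest. In TRAMP against wild type at 24 weeks, however, luminal markers did not follow proliferation (median -0.04, against 2.48 for DNA replication genes). The luminal test therefore does not cover a change in the share of dividing cells, which was not tested. An effect of the diet on cell division and variation between animals both stay open as hypotheses, since the mitosis median at 24 weeks was 0.00 without PEITC replicate 1.

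Of the 100 genes that exceeded 16-week TRAMP prostates on control diet most in the tumor, 98 were lower with PEITC than on control diet at 24 weeks (median -0.75), against 47.3% of all tested genes, although 0 of the 100 passed the test. The genes are not independent replicates, so the count does not measure the spread between animals, and variation between animals stays open. GC content bias as the whole cause was argued against by 98 of 98 genes lower after the correction (median -0.73). Dependence of the direction on 1 control library was argued against by at least 98 lower against each alone, with 97 and 95 lower for PEITC replicates 0 and 1 alone. These counts give the direction and not the size of the differences. Tumor tissue in the 24-week control prostates remains a candidate explanation. Of the 100 genes furthest below 16-week TRAMP prostates on control diet in the tumor, 79 were higher with PEITC at 24 weeks (median 0.24). The control excess was a median of 14.6% of the tumor excess (quartiles 9.37% and 22.7%), whereas 1 share of admixed tumor would give like percents. It was 71.0% for Saa1, but the SD of Saa1 on control diet exceeded its mean, so that percent does not weigh on admixture. An acute-phase response may also contribute and was not tested: Lrg1 stood at 77.4 FPKM and Saa1 at 19.7 in wild type 24-week replicate 0, and at 80.6 and 26.5 in the 16-week wild type library, which hold no transgene.

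Seminal vesicle genes stood far above the other libraries in the 16-week wild type library, where they made 1.67% of its FPKM sum. Of the 9 genes, 8 exceeded 10 times their highest value elsewhere, Svs2 with 3095 FPKM against at most 3.04, as seminal vesicle tissue in that library may give; the exception was Ceacam10, with 2.77 FPKM against 4.77. The age of the wild type mice cannot be told apart from this, because there was 1 wild type library of 16 weeks. Sampling of adjoining tissue stays a hypothesis.

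Other splits of the same libraries were counted for the comparisons of both ages. With PEITC the real count was 0 genes, which all 35 splits of the 8 TRAMP libraries reach by definition, so the count decides nothing; the highest other split gave 1. For TRAMP against wild type, 1 of 35 splits, the real one, gave as many as its 5830 genes in a fit with 2 groups, and the highest other split gave 2. The other splits mix the genotypes, which widens the spread within their groups and keeps their counts low. The share of 1 of 35 met the bound set beforehand for arguing against chance. It is also the smallest share possible with 35 splits, so this count alone did not exclude chance.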

How the results depend on the processing

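The GC correction, the 24-week wild type libraries as control at 16 weeks, the TRAMP effect of the other age and the 50 column orders in fry were chosen after seeing the data. Named genes kept both call and direction, or stayed uncalled in either direction, in 13384 tests. They lost the call in 543, gained it in 146 and reversed direction with a call in either fit in 8. Counts stayed within 1.5 times their value and relations within an r of 0.1, a bound not taken from replicates, in 220 tests; 44 counts were lower, 35 higher, 7 relations moved further and 1 reversed. FPKM values give no read depth, so the precision of low values is unknown. Every gene list call was lost with an estimated correlation, giving 0 lists in each of the 10 comparisons. This included DNA replication genes in TRAMP at 24 weeks (adjusted p = 0.428), of which all 20 were called. A call lost with that setting therefore does not tell weak lists from strong ones. Where no cause is stated for a change given here, the cause was not tested.

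Hoxb13 turned to 0.052 in TRAMP at 24 weeks with quantile normalization. With the 24-week wild type libraries as control, Svs6 turned to 0.044, Tnnt3 to 0.65, Tnni2 to 0.69, Myl1 to 0.24, Emcn to 0.11 and Fosb to 0.21 at 16 weeks, and Ccl20 to 0.036 for both ages. With the TRAMP effect of the other age, the relation of the PEITC to the TRAMP effect turned to 0.195 at 24 weeks and moved to -0.0064 at 16 weeks. That setting also changes the genes, the sharing of libraries and the relation to GC content.

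Fitting only the groups compared, which leaves fewer samples for the spread, called 2198 genes in TRAMP at 16 weeks, 1 with PEITC at 24 weeks, 0 with PEITC at 16 weeks, 0 for age, 0 for the difference of the PEITC effect and 0 in the tumor. Without a filter, more genes were tested: 9 were called with PEITC at 24 weeks, 6 at 16 weeks and 9 for both ages, 4 for age, 12 for the difference of the PEITC effect and 297 for that of the TRAMP effect. A pseudocount of 0.1 gave 2 genes with PEITC at 16 weeks and 27 for the difference of the TRAMP effect. A minimum mean of 2 FPKM gave 27 for the latter. Without the intensity trend 0 genes were called with PEITC at 16 weeks and 0 for the difference of the PEITC effect.

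With the replicate number as a block, 3986 genes were called in TRAMP at 24 weeks, 65 with PEITC at 24 weeks, 0 at 16 weeks, 3 for both ages, 99 for age, 49 for the difference of the PEITC effect and 902 in the tumor. Lists called were 5 for age, 3 of them among the 9 called without the block, and 6 with PEITC at 24 weeks, 2 of them among the 8. The block was not used elsewhere, since the numbers did not pair the libraries: over 6 pairs of groups the differences within groups correlated at -0.31 to 0.28.

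Fry called 0 lists with PEITC at 24 weeks, 0 at 16 weeks, 0 for both ages, 1 for age, 0 and 1 for the differences of the PEITC and TRAMP effects and 4 in the tumor. Its p-values depend on the order of the group columns, and over 50 orders each count moved by at most 1 list. After the GC correction 5 lists were called with PEITC at 24 weeks and 14 for the difference of the TRAMP effect.

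Leaving out each library in turn, with a lone library assumed to vary like the other groups, gave 0 to 160 genes with PEITC at 24 weeks, 0 to 0 at 16 weeks and 0 to 16 for both ages, 1 to 260 for age, and 0 to 124 and 33 to 82 for the differences of the PEITC and TRAMP effects. The TRAMP counts were 4200 to 4950 at 24 weeks, 3615 to 3655 at 16 weeks and 6440 to 6707 for both, and the tumor count 1050 to 1217. Lists called were 7 to 14 with PEITC at 24 weeks, 5 to 13 at 16 weeks and 3 to 15 for both, 5 to 17 for age, and 2 to 10 and 7 to 16 for the differences. The relation ranged from -0.327 to -0.0618 at 24 weeks and from -0.320 to -0.0687 at 16 weeks.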

Other observations

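The values given here were chosen after the results were seen. Neuroendocrine transcripts stood out in 1 PEITC library. In TRAMP PEITC 24-week replicate 1, Chga stood at 12.4 FPKM, the transcription factor gene Insm1 at 10.8, the synaptic genes Snap25 at 3.01 and Syp at 3.23. In the 16-week wild type library Snap25 stood at 3.76 FPKM and Syp at 2.70.

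Cyp2b10, which metabolises foreign compounds in the liver, followed the groups closely. It stood at 109 ± 1.37 FPKM in wild type prostates at 24 weeks (SD, n = 2) and at 113 FPKM at 16 weeks. In TRAMP mice it stood at 47.6 ± 1.42 and 25.7 ± 2.26 at 16 weeks on control and PEITC diet, at 14.4 ± 0.369 and 19.8 ± 1.38 at 24 weeks (n = 2 each), and at 10.9 in the tumor.

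The mean log2(FPKM + 1) of the 40 proliferation genes was 4.27 in the tumor, 1.66 and 1.61 in the 24-week wild type libraries and 2.33 in the 16-week wild type library.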
